A study of Mus musculus with 2 samples.

How the data were processed

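The series holds 2 RNA-seq libraries of CD45-negative cells sorted from mouse tumours, 1 for hosts with wild-type Mtdh and 1 for hosts without it. The sample titles speak of tumours and mice in the plural and do not say how many went into each library. Per the labels' protocols, Py8119 tumours were dissociated, red blood cells were lysed, and live cells negative for CD45 were collected by flow cytometry. RNA was extracted with a column kit for small samples, ribosomal RNA was removed, and libraries were built with the PrepX chemistry on an automated system, per the labels' protocols. The labels give wild-type Mtdh for the injected tumour cells of both libraries, so the 2 libraries are named here for the host.

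The authors deposited 1 table of log2 values, with 1 column per library and 12707 genes, each of them annotated as protein coding. STAR 2.7.8a, Partek and the mouse build mm39 are listed in the submitters' processing notes. The role of Partek, the release of the gene annotation, strand handling, and the treatment of duplicate and multiply mapped reads are not given in the sources used here. The name of the table describes its values as log2 of FPKM + 1 (fragments per kilobase of length, scaled to the library total).

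The values were checked against that description. When each deposited log2 value was turned back into FPKM and multiplied by the gene length column of the table, each library summed to 1000000. The length column equals the distance from start to stop in 100% of rows, so the authors' FPKM values used the genomic span of each gene, introns included, and the listed genes as the library total. This has a large effect on the measurements. For a gene with a long span, most FPKM values are under 1, where the added 1 hides much of a difference. Differences in the deposited log2 values therefore understate the ratios of long genes and of low genes, and levels of different genes cannot be compared as for values per kilobase of transcript.

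Reads were recovered from the same values. Low values of each library fall on whole multiples of 1 step, which gave 26069378 reads for the library from the wild-type host and 23381862 for the library from the knockout host. Among values under 1000 reads, 84.9% and 83.4% were whole within 0.1 read. The others were fractions, so the authors' counting shared some reads between genes, and genes with near-identical copies (histones, ribosomal proteins, Tgtp1 and Tgtp2, class I genes of the H2-Q group) are uncertain. No listed gene had under 10 reads over both libraries, which points to a filter on the table that the sources used here do not give. A gene missing from the table was not analysed here. Values of 0 were given for 511 genes in the library from the wild-type host and 413 in the other, and they include genes that every cell uses, such as Rps27 and Timm13. A value of 0 is therefore reported only as listed at 0, and no ratio is given for it.

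With 1 library per group there is no replicate, so no p-value, standard error or error model was computed. The size rules below were fixed before the data were examined. A gene was counted as higher or lower in the library from the knockout host when its deposited log2 value differed by 1 or more, among genes with a mean of 1 or more over both libraries. For each of 49 gene lists fixed from general knowledge, the median difference was taken over members with a mean log2 value of 0.5 or more. The lists cover immune genes, lipid metabolism, tumour cell programmes, stroma, stress responses, RNA quality, sex-linked genes and markers of other cell types. The median was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5. Lists with fewer than 5 such members have values only. About 1 list in 20 would stand apart by chance if its members varied independently. Lists share members, and genes of a list that vary together would stand apart more often. The percentile describes these libraries and not the host genotypes.

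The genes named in the text followed a rule set at the same time. It takes Mtdh and the 15 genes with the largest higher and the 15 with the largest lower difference among genes at FPKM 5 or more in a library. It leaves out predicted, unnamed, mitochondrial and small RNA symbols. From each list it takes the 3 members with the largest difference in size and the 2 with the highest mean, and it also takes the 5 genes with the highest level in each library. Some genes that the rule takes are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

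Ratios printed as folds are ratios of recovered RPM (reads per 1000000 recovered reads). Their 95% counting intervals are exact conditional binomial (Clopper-Pearson) intervals of those reads. PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. The read scale used for list medians is the log2 ratio of RPM with 0.1 added, over genes with 100 or more reads in the 2 libraries together; it was added after the data had been seen. Spread between the libraries was compared with Poisson draws at the same read totals, by class of total reads.

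Alternatives fixed before the data were seen were pseudocounts of 0.1 and 5, median centring, FPKM rescaled to 1000000, quantile normalization, a trimmed mean of log ratios (30% and 5% trimmed), and rescaling without mitochondrial, ribosomal protein, histone and small RNA genes. Others fixed then were no filter or a mean of 3 or more, thresholds of 1.5-fold and 3-fold, named symbols only, genes whose difference exceeds counting error, random lists of named symbols, and means in place of medians. Read-scale values, the same values for genes with 3000 reads or more, and genes with whole reads only were added after the data had been seen. A reference annotation of another build was at hand and no coordinates were taken from it; coordinates given are those of the table, counted from 1, on mm39.

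The steps were tested on simulated data. Simulated tables of 12707 genes gave back their read totals with a ratio of 1. Of 200 genes raised among 6057 simulated genes, the size rule called 29% of those raised 2-fold and 88% of those raised 4-fold. The expression filter was then applied again to the simulated values, which moved a few genes across it. Of the 5859 genes that passed and had not been raised, whose differences were shuffled real ones and so kept the real extremes, it called 4.92%. Of simulated lists of 20 genes, 5.50% stood apart with no shift and 100% with a shift of 0.5. Their members were drawn at random from shuffled differences, so this rate does not cover lists whose genes vary together. The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.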

Results

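RNA was sequenced from CD45-negative live cells of Py8119 tumours grown in mice with wild-type Mtdh and in mice lacking Mtdh. Py8119 is a mouse mammary tumour line derived from a tumour of the MMTV-PyMT model and has a mesenchymal character. Mtdh (metadherin) is a gene that promotes growth and metastasis of mammary tumours. The tumour cells carried Mtdh in both libraries, so the design asks how the tumour compartment differs when the host lacks the gene. The gate removes most leukocytes and leaves tumour cells with any fibroblasts, pericytes and endothelial cells of the host. There was 1 library per host genotype, with 26069378 recovered reads for the wild-type host and 23381862 for the knockout host. No difference below has a replicate check, and each describes this pair of libraries rather than the genotypes.

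Among the gene lists, interferon-response and antigen-presentation genes were higher in the library from the knockout host, and collagen, matrix and histone genes were lower by their medians. Most of the single genes counted below lie outside these lists. Of 6057 genes with a mean log2(FPKM + 1) of 1 or more, 140 were higher by 1 or more in the library from the knockout host (2.31%) and 160 were lower (2.64%). The median difference of these genes was -0.03, and Pearson's r of the log2 values across all 12707 listed genes was 0.95, where genes are not independent replicates. The highest FPKM values, which use the genomic span and so favour short genes, were those of mt-Co2, mt-Nd3, mt-Co1, Actb and Actg1 in both libraries. Among the genes counted as higher, 16 belonged to the interferon gamma list, 7 to the class I presentation list and 4 to the histone list. Among those counted as lower, 13 belonged to the histone list and 6 to the collagen and matrix list. The interferon gamma and class I lists share members, so a gene such as Tap1 enters both counts. The counts depend on the added 1: with 0.1 added they were 285 and 332, and with 5 added they were 41 and 30.

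**Figure D1:**
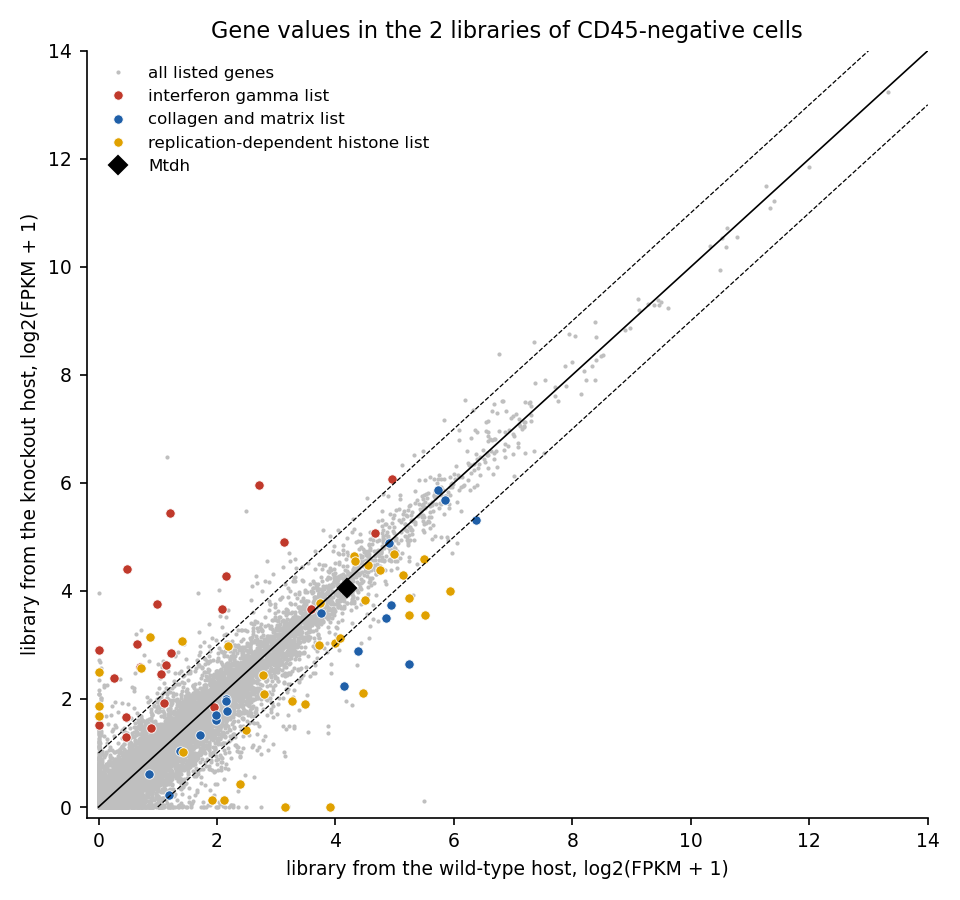
Each point is a gene, with its log2(FPKM + 1) in the library from the wild-type host on the x axis and in the library from the knockout host on the y axis; the solid line marks equal values and the dashed lines a difference of 1. Interferon gamma list members lie mostly above the upper dashed line (18 of 24), 6 of 19 collagen and matrix members lie below the lower one, and Mtdh lies near the line of equal values.

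Mtdh itself (ENSMUSG00000022255, chromosome 15, 34082840 to 34145770, plus strand) was at FPKM 17.3 in the library from the wild-type host and 15.7 in the library from the knockout host, a log2 difference of -0.13. The recovered reads were 28376 and 23130, a ratio of 0.909 (95% counting interval 0.893 to 0.925). The injected cells carry the gene in both, so this level checks the host label only as far as host cells contribute RNA. Among the 500 genes nearest to it in total reads, 125 had a ratio as low or lower. The list of metastasis-associated genes and MTDH partners had a median difference of 0.07 over 10 members (percentile 75.7), and 0 of them passed the size rule. Bccip was at 0.59, Nfkb1 at 0.44, Ctnnb1 at -0.30 and Eif4g1 at 0.03.

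Interferon gamma response genes had the largest median difference in log2(FPKM + 1) among lists with 5 or more measured members. Of the 24 measured members, 18 were higher by 1 or more in the library from the knockout host, 0 were lower and 6 lay between. The median difference was 1.60, above the median of every one of the 10000 matched random lists, whose highest was 0.32. Iigp1, an immunity-related GTPase that acts on intracellular parasites, was at FPKM 1.30 and 42.7, and its reads were 32.8-fold higher (564 and 16576 reads, 95% counting interval 30.1 to 35.7). Igtp, of the same family, was at 82 and 3789 reads, and Gbp2, a guanylate-binding protein, at 2530 and 24901 reads (95% counting interval of the ratio 10.5 to 11.4). Irgm1 was 5.34-fold higher, and Gbp3 12.6-fold. Irf1, a transcription factor that drives much of this response, was at FPKM 30.1 and 66.1. Psme2, a proteasome activator subunit, was at 24.3 and 32.5. Socs1, the feedback inhibitor of the pathway, chosen after its values were seen, was at -0.11. Tgtp1 and Tgtp2 are near-identical neighbours, listed at 1.1 and 1351 reads and at 180.9 and 2044 reads, so the split between them is uncertain. Of the 24 members, 7 are also in another list. Pan-leukocyte markers did not move with this group: their 8 members with 100 reads or more had a median log2 read ratio of -0.003 (quartiles -0.20 and 0.41), against 2.25 (quartiles 1.86 and 3.64) over the interferon gamma members counted the same way.

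The type I interferon list was also higher, with a smaller difference. Its 17 measured members had a median of 0.79, above every matched random list. Of these, 3 were higher by 1 or more: Ifi27l2a at 1.36, Ifi44 at 1.34 and Bst2, an antiviral membrane protein, at 1.07. The other 14 lay between, with Ifit1 at 0.91, and 5 of the 17 were below 0. On the read scale the median was 1.07 over 27 members, of which 18 were 2-fold higher and 1 was 2-fold lower. The median was 0.31 without the expression filter and 0.29 with 5 added, still above the matched random lists.

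Most genes that load and display peptides on MHC class I were higher, with 16 members above 0 and 3 below. The list of 19 measured members had a median of 0.73, above every matched random list, with 7 higher by 1 or more and 0 lower. Of the 19 members, 4 are also in another list, and Tap1 and Psmb8 are shared with the interferon gamma list. H2-Q7 was at FPKM 0.644 and 8.66, Tap1, a subunit of the peptide transporter, at 3.23 and 11.7, and the immunoproteasome subunit Psmb8 had 117 and 455 reads. H2-D1 had 9815 and 18160 reads (2.06-fold) and B2m, the light chain of class I, had 14707 and 19612 reads (1.49-fold). The general chaperones of the list were on the other side of 0, with Calr at -0.12 and Canx at -0.20; both were chosen after their values were seen. For class II only 2 members passed the expression filter. H2-Aa was at FPKM 0.181 and 1.71 with 24 and 203 reads, and H2-Ab1 at 0.0752 and 0.955 with 23 and 262 reads. On the read scale, 5 class II members had a median log2 ratio of 3.52 (percentile 99.8).

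Chemokine and checkpoint genes were higher as well. The 12 measured chemokines and cytokines had a median of 0.68, above every matched random list, with 3 higher by 1 or more and 0 lower. Cxcl10, which attracts activated T cells, was at FPKM 7.72 and 28.8, and Ccl2, which attracts monocytes, at 72.1 and 185.3. Cxcl9 was listed at 0 in the library from the wild-type host and had 290.8 reads in the other. Cxcl1 was at 0.68. The 8 measured checkpoint ligands and suppressors had a median of 0.42 (percentile 99.8), but without the expression filter it was 0.11 and inside the random range. Cd274, which encodes PD-L1, was the only one higher by 1 or more, with 580.5 and 2170 reads, 4.17-fold. Pvr was at 0.67, Lgals9 at 0.50, Ptgs2 at 0.44 and Cd47 at 0.08. Lists overlap here: 6 of the 12 chemokines and 2 of the 8 checkpoint genes sit in another list too, among them Ccl2, Cxcl1, Cxcl2 and Lif in the NF-kB list. The NF-kB list and the immediate early list, which respond to tissue dissociation as well, were also higher (medians 0.42 and 0.39).

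**Figure D2:**
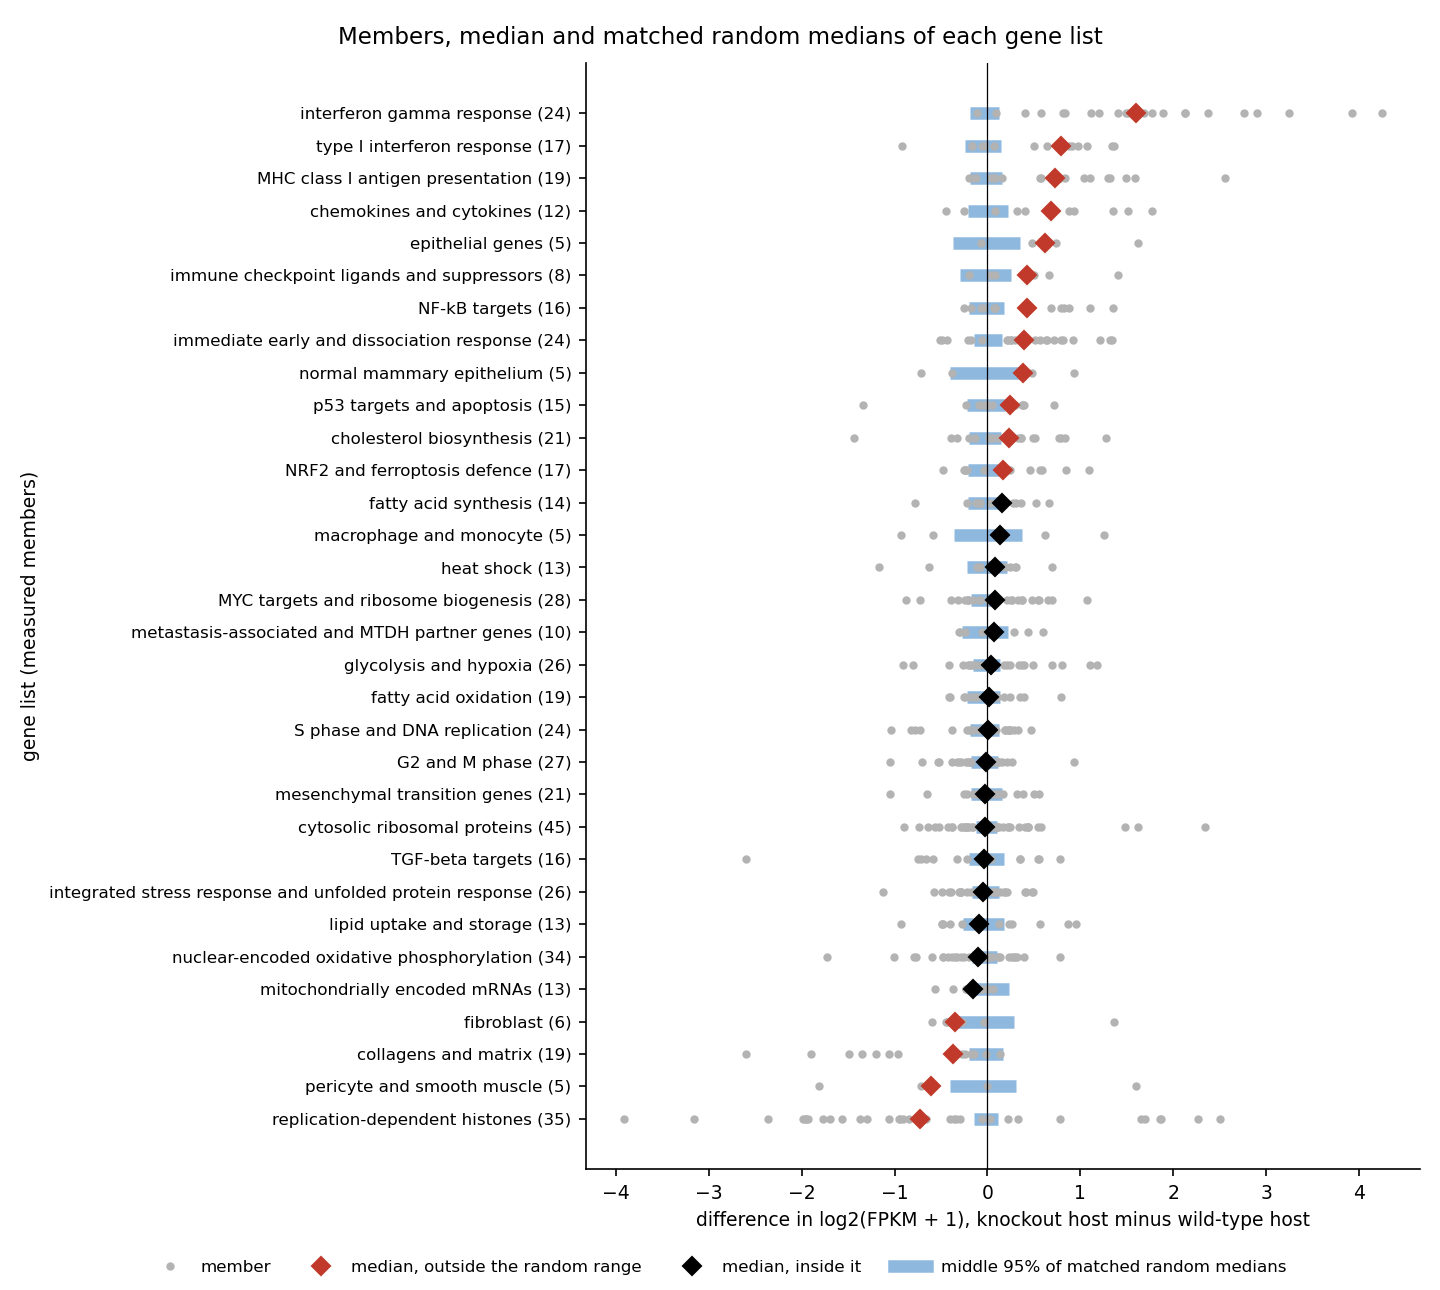
Each row is a gene list with 5 or more measured members; grey points are the members' differences in log2(FPKM + 1) (knockout host minus wild-type host), diamonds the list median, red where it stands apart, and blue bars the middle 95% of medians of matched random lists. Of 32 lists, 12 stand apart on the higher side, led by the interferon gamma response at 1.60, and 4 on the lower side, down to -0.73 for the replication-dependent histones. By chance 1.6 of the 32 would do so if list members varied independently, and more would if they vary together.

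Lipid genes were examined because the series concerns lipid metabolism of the host. Cholesterol biosynthesis was slightly higher, with a median of 0.23 over 21 members (percentile 99.8); 1 member was higher by 1 or more and 1 was lower. Insig1, a sterol-regulated brake on this pathway, was at FPKM 8.93 and 23.1. Hmgcs1, an early enzyme of the pathway, was at 19.0 and 34.6. Tm7sf2, a sterol reductase, was lower, with 273 and 9 reads. The list did not stand apart by its mean (0.20, percentile 96.9) or among genes with whole reads only (0.11). Fatty acid synthesis had a median of 0.16 over 14 members (percentile 95.8), with 0 past the size rule. On the read scale its median was 0.31 (percentile 99.8), which stands apart. Acsl4 was at 0.66, Srebf1 at 0.52, Elovl1 at -0.78, Scd2 at -0.13 and Fasn at 0.04. Fatty acid oxidation, at 0.02 over 19 members (percentile 75.7), and lipid uptake and storage, at -0.09 over 13 (percentile 35.0), did not stand apart, and 0 members of either passed the size rule. Acads was at 0.79, Decr1 at -0.41, Hadh at -0.41, Echs1 at 0.18 and Acadvl at -0.14. In the uptake and storage list, Hilpda was at 0.96, Dgat1 at 0.87, Plin2, which coats lipid droplets, at 0.57, Fabp5 at -0.09 and Apoe at -0.93. Its median stood apart on the lower side under quantile normalization (-0.23) and with whole reads only (-0.33).

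Collagen and matrix genes were lower in the library from the knockout host. Their 19 measured members had a median of -0.37 (percentile 0.03), with 6 lower by 1 or more, 0 higher, and 18 of the 19 below 0. Col1a1, a chain of type I collagen, was at FPKM 36.7 and 5.24 with 16111 and 2059 reads, 7.02-fold lower (95% counting interval 6.70 to 7.35). Postn (periostin) had 13035 and 2625 reads, and Bgn (biglycan) 6347 and 1837. Col6a1 was at -1.06. Thbs1, another matrix protein, was at 0.13. Which of the sorted cells made these RNAs was not tested. Markers of stromal cells gave a mixed picture beside these genes. The pericyte and smooth muscle list had a median of -0.61 over 5 members (percentile 0.61): Pdgfrb had 9206 and 1691 reads, 4.88-fold lower, and Acta2 was at -0.71, while Gja4 had 1 and 127 reads (142-fold, 95% counting interval 24.96 to 5636). Gja4 is among the genes with 100 to 300 reads in total, of which 18.0% had 5 reads or fewer in 1 library. The pericyte and smooth muscle list was inside the random range without the expression filter (-0.14) and as a mean (-0.31). Under the other 9 of its 11 alternatives it still stood apart, with a median of -1.74 on the read scale. The fibroblast list had a median of -0.35 over 6 members (percentile 2.10). Dcn was at -0.60, Serpinf1 at -0.45, Gsn at -0.43, Ogn at -0.27 and Ly6c1 at 1.36. That list was inside the random range under 7 of its alternatives. Of endothelial genes only Plvap (-0.73) and Ecscr (-0.33) passed the expression filter. The 7 endothelial members with 100 reads or more went both ways: 3 were above 0, 2 were 2-fold higher and 3 were 2-fold lower. Their median log2 read ratio was -0.93 (quartiles -1.63 and 2.82), inside the random range.

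Most leukocyte markers were low in both libraries, while a few markers of other lists, such as Lyz2 and Fscn1, were well expressed. Over all 16 listed pan-leukocyte genes the sums were 43.1 and 42.7 RPM (reads per 1000000 recovered reads), and Fcer1g, the only measured one, was at FPKM 0.248 and 0.624. The T and NK cell genes summed to 3.95 and 2.44 RPM, the B and plasma cell genes to 1.61 and 1.92, and the mast cell and basophil gene listed to 0 and 2.48. Macrophage and monocyte genes had a median of 0.14 over 5 members (percentile 82.6): Lyz2 was at FPKM 26.9 and 29.7, Mpeg1 at 1.25, Cd68 at 0.62, Cd14 at -0.59 and Apoe at -0.93. Of the remaining marker lists, neutrophil genes had a median of -0.28 over 4 members (Mmp9 -0.43), platelet genes -1.17 over 3 (Gp1bb -1.29, Ppbp 53 and 1 reads), erythroid genes -0.15 over 2 and Schwann cell genes -0.36 over 2 (Pmp22 -0.72). The dendritic cell list had Fscn1 alone past the expression filter, at -1.24, and the skeletal muscle list Eno3 alone, at -0.02. On the read scale, 3 dendritic cell genes had a median log2 ratio of 0.97, with 2 above 0. Of these 3, 1 was 2-fold higher and 1 was 2-fold lower. For keratinocytes, Krt10 was at -0.12 and Lgals7 was listed at 244 and 0 reads. No adipocyte, hepatocyte, lymphatic endothelial or sex-linked gene passed the filter; these lists summed to 5.07 and 3.54, 7.35 and 3.68, 1.34 and 19.5, and 3.45 and 9.76 RPM. The normal mammary epithelium list had a median of 0.38 over 5 members (percentile 97.6), with Areg, an EGF receptor ligand, at 0.94 and Krt8 at 0.48, and was inside the random range under 7 of its alternatives.

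**Figure D3:**
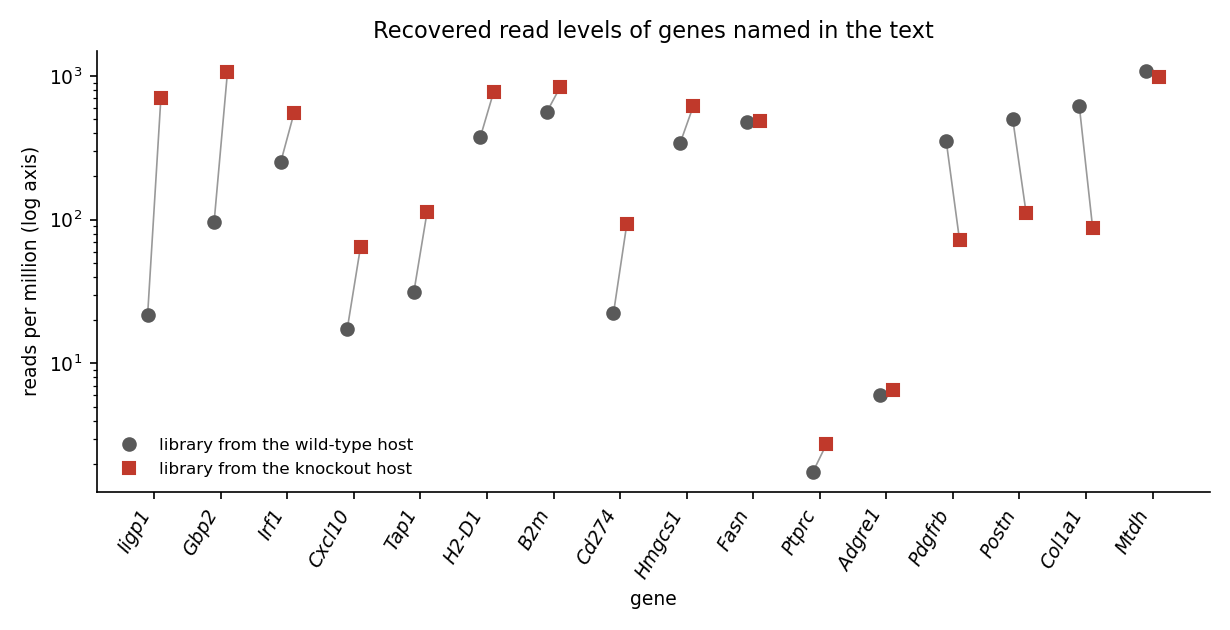
RPM on a log axis for genes of the text, grey circles for the library from the wild-type host and red squares for the library from the knockout host, 1 library each. Interferon-response and class I genes are higher in the library from the knockout host (Iigp1 21.6 and 709), Col1a1, Postn and Pdgfrb are lower (Col1a1 618 and 88.1), and Ptprc and Adgre1 (leukocyte genes chosen after their values were seen) are near the bottom of the axis in both.

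Cell cycle, MYC target, mesenchymal and glycolysis lists, chosen as tumour cell programmes, did not stand apart between the 2 libraries, while epithelial genes did. Tumour and host cells were not separated within the sorted cells. S phase genes had a median of 0.01 over 24 members (percentile 69.2), with Tyms at -1.04, Mcm7 at -0.83, Rfc4 at -0.78, Pcna at -0.19 and Rrm1 at 0.25. G2 and M phase genes had a median of -0.01 over 27 (percentile 58.0), with Cdc20 at -1.05, Aurkb at 0.94, Hmmr at -0.70, Top2a at 0.06 and Ccnb1 at -0.28. The MYC target and ribosome biogenesis list was at 0.08 (percentile 92.2), with Srm at 1.08, Nop16 at -0.88 and Odc1 at 0.70. Mesenchymal genes were at -0.03 over 21 (percentile 42.4). Vim, the intermediate filament of mesenchymal cells, was at FPKM 356.2 and 326.6, Lgals1 was at -0.65 and Mmp2 at -1.05. The 5 measured epithelial genes had a median of 0.62 (percentile 99.8), with Cldn4, a tight junction protein, at FPKM 5.30 and 18.4, Krt19 at 0.73, Krt18 at 0.62 and Krt8 at 0.48; without the expression filter this list was at 0.06 and inside the random range. Glycolysis and hypoxia genes were at 0.04 over 26 (percentile 76.9). In that list Vegfa, the vascular growth factor, had 15765 and 32582 reads and Hk2, a hexokinase, 3793 and 8644, while Egln3 was at -0.91, Gapdh at -0.09 and Tpi1 at 0.24.

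Nuclear genes of oxidative phosphorylation had a median of -0.10 over 34 members (percentile 16.1), with Uqcrq at -1.73, Cox6a1 at -1.01, Ndufs1 at -0.79 and Atp5b at 0.00. The 13 mitochondrially encoded mRNAs had a median of -0.15 (percentile 6.64). It stood apart on the lower side on the read scale and with a mean log2 value of 3 or more. mt-Atp8 was at -0.56, mt-Nd4 at -0.37 and mt-Co2 at -0.10. These RNAs took 2.08% and 1.88% of reads. Cytosolic ribosomal protein genes were at -0.03 over 45 (percentile 34.5). Of these, Rpl13 was at 1.62, Rpl5 had 1836 and 4955 reads and Rplp1 was at 0.03, and Rps27 was listed at 0 and 107.9 reads. Ribosomal protein genes have many processed copies in the genome, so single values are uncertain.

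Immediate early and NF-kB genes, which also respond to tissue dissociation, were higher in the library from the knockout host. The immediate early list had a median of 0.39 over 24 members, above every matched random list, with 3 higher by 1 or more and 0 lower. Fosl1, an AP-1 subunit, was at FPKM 7.63 and 20.8, Klf2 at 8.45 and 22.6 and Egr3 at 33.8 and 79.4. Fos, with the highest mean log2 value of the list on a scale that favours short genes, was at -0.18 and Zfp36 at 0.30. The NF-kB target list had a median of 0.42 over 16 (percentile 99.96). Tnfaip3, a feedback inhibitor of NF-kB, was at 43.7 and 95.2, Lif at 28.5 and 53.1 and Ccl2 as above; 7 of the 16 sit in another list, and with whole reads only the median was 0.18 and inside the random range. p53 targets were at 0.25 over 15 (percentile 99.4), with Cdkn1a, a cyclin-dependent kinase inhibitor, at 0.72, Trp53inp1 at 0.39, Btg2 at 0.37 and Bax at -1.34. The NRF2 and ferroptosis list was at 0.17 over 17 (percentile 97.54), just past the rule, with Srxn1 at 1.09, Gpx4 at 0.85, Pgd at 0.59 and Fth1 at 0.12. Both lists were inside the random range under several alternatives, and the second turned negative with whole reads only (-0.13). Heat shock genes were at 0.08 over 13 (percentile 80.5; Hspa1b -1.17, Hspa8 0.08). The integrated stress and unfolded protein response list was at -0.05 over 26 (percentile 35.9; Ddit3 -1.12, Atf4 0.48). TGF-beta targets were at -0.03 over 16 (percentile 41.1; Col1a1 -2.60, Skil 0.79, Id2 -0.74), and stood apart on the lower side with a mean log2 value of 3 or more (-0.28) and with whole reads only (-0.33).

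Replication-dependent histone genes were lower. Of 35 measured members, 13 were lower by 1 or more, 6 were higher and 16 lay between, with a median of -0.73, below every matched random list. Summed over the list, they had 473.8 and 281.0 RPM. H2bc8 had 965.6 and 216.7 reads, and H3c3 had 727.4 and 339.4. H2ac15 was listed at 144 and 0 reads, H4c9 at 150 and 0, and H3c2 at 0 and 67.6. Copies of these genes are near-identical, so values of single copies are uncertain: H2ac18 had 671.4 and 1.1 reads and its neighbour H2ac19 0 and 179.1. These mRNAs lack poly(A) tails, so their level would depend on a selection by tail. The labels' protocols give removal of ribosomal RNA instead, and why this list was lower was not tested.

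The 15 largest differences on the higher side, apart from those above, included Cycs (cytochrome c) with 319.1 and 1420, Coa3 with 21 and 163, Mrpl53 with 13 and 172.5, H2ac8 with 15.3 and 129.2 and Mocs3 with 1 and 250 reads (279-fold, 95% counting interval 49.6 to 11053). On the lower side they included Bdkrb1, a bradykinin receptor, with 480 and 51 reads, Selenoh with 750 and 98, Wdr83os with 443.9 and 60.9, Commd4 with 443 and 36, Rps26 with 787.1 and 81.3, Rpl12 with 764.6 and 90.2, Rps21 with 380 and 46, H4c3 with 452 and 63.4 and H3c15 with 455.9 and 68.6. Sap18b was listed at 167.7 and 0.1 reads and H3c14 at 270.1 and 0. Many of these genes have under 1000 reads in total. Mocs3 is among the genes with 100 to 300 reads, of which 288 of 1599 (18.0%) had 5 reads or fewer in 1 library. Among genes with 300 to 1000 reads in total, the spread of the log2 read ratio was 0.97, which is 8.30 times that of counting error.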

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

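No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out in turn. The alternatives on the read scale and with whole reads only were chosen after the data had been seen. Median centring shifts a list and its random lists alike, so it could change a percentile only through the random draw. Of 419 alternative list medians, those with median centring included, 375 stayed on their side of the percentile rule. The interferon gamma, type I interferon, class I presentation, chemokine, immediate early, histone and collagen lists did so under every alternative that gave a value; the interferon gamma median ranged from 0.82 to 2.30 and the collagen median from -1.13 to -0.16. Mtdh stayed within a difference of 1 under its 8 alternatives. Of 229 alternative values of the genes with the 15 largest differences, 2 fell under 1 in size, Coa3 and Commd4 with 5 added. These genes were picked as the extremes of the same values, so this says little about how firm their differences are. Lists with fewer than 5 members under an alternative have no value there. Over the scaling and pseudocount alternatives the median difference of the counted genes lay between -0.07 and 0.02, against -0.03 for the deposited values.

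The counts of higher and lower genes, 140 and 160, became 285 and 332 with 0.1 added, 41 and 30 with 5 added, 293 and 322 after rescaling to 1000000 (which works as a smaller pseudocount), and 266 and 333 after the same rescaling without mitochondrial, ribosomal protein and histone genes, so most of that move came with the rescaling. With a mean of 3 or more they were 39 and 28, at 1.5-fold 412 and 489, at 3-fold 53 and 52, on the read scale 959 and 1282 of 10814, with 3000 reads or more 67 and 42, and with whole reads only 90 and 111, where fewer genes enter. Higher genes made up 46.7% of the counted ones, but 57.7% with 5 added, 58.2% with a mean of 3 or more and 61.5% with 3000 reads or more. Every one of the 300 counted differences exceeded counting error. These genes were picked for the size of their difference in the same values, so this says little about how firm the differences are. Over the classes of total reads, the spread between the libraries was itself 8.30 to 14.4 times counting error among all genes of a class.

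For the lists below the cause was not tested. Without the expression filter the medians moved inside the random range for checkpoint genes (0.11), epithelial genes (0.0649), p53 targets (0.0290), NRF2 genes (0.12), fibroblast (-0.0410), pericyte (-0.14) and normal mammary genes (0.0765). As means, so did cholesterol biosynthesis (0.20), p53 targets (0.0860), NRF2 genes (0.18), fibroblast (-0.0712), pericyte (-0.31) and normal mammary genes (0.14). With 0.1 added, NRF2 genes (0.19), fibroblast (-0.38) and normal mammary genes (0.51) did; after rescaling to 1000000 the same 3 lists were at 0.21, -0.36 and 0.53, and, rescaled without mitochondrial, ribosomal protein and histone genes, at 0.16, -0.42 and 0.47. Normal mammary genes did with 5 added (0.12) and fibroblast genes with the trimmed mean (-0.30). With a mean of 3 or more, NRF2 genes did (0.18), while mitochondrial mRNAs (-0.15) and TGF-beta targets (-0.28) came to stand apart. Lipid uptake and storage came to stand apart under quantile normalization (-0.23). On the read scale, p53 targets (0.12), NRF2 genes (0.12), fibroblast (-0.28) and normal mammary genes (0.51) moved inside, and fatty acid synthesis (0.31) and mitochondrial mRNAs (-0.15) came to stand apart. With 3000 reads or more, p53 targets (0.14) and NRF2 genes (0.21) were inside, and fatty acid synthesis (0.28) and mitochondrial mRNAs (-0.15) outside. With whole reads only, cholesterol biosynthesis (0.11), p53 targets (0.16) and NF-kB targets (0.18) moved inside, lipid uptake (-0.33) and TGF-beta targets (-0.33) came to stand apart, and NRF2 genes turned to -0.13.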

Other observations

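The genes of the first 3 paragraphs and the tests below were chosen after the values had been seen, except that the scaling and pseudocount alternatives had been fixed before and only the bounds set on them came after. Several interferon-induced genes outside the fixed lists were higher in the library from the knockout host. Gvin1, a very large interferon-induced GTPase, had 443.6 and 5706 reads (14.3-fold) and Gvin2 had 491.2 and 3873. The immunity-related GTPase genes Gm4841 and F830016B08Rik had 52 and 2412 and 148 and 1619 reads, and Gbp9 had 479 and 1636. Class II genes below the expression filter pointed the same way: H2-DMa had 20 and 354 reads, H2-DMb1 had 2 and 112 (62.4-fold, 95% counting interval 16.9 to 521.9), and Ciita, the master regulator of class II genes, was listed at 0 and 73 reads. Cd74, the class II chaperone, had 9 and 21 reads. The fold of H2-DMb1 is uncertain beyond its counting interval. Among genes with 100 to 300 reads in total, 288 of 1599 (18.0%) had 5 reads or fewer in 1 library.

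Among genes with 3000 reads or more in total and outside the lists, some of the largest differences on the higher side were these. Nr4a3, an orphan nuclear receptor, had 2412 and 8180 reads. Pim1, a kinase induced by cytokines, had 864 and 2813, Has2, which makes hyaluronan, had 4068 and 11296, Rel had 2029 and 5054, and Sox9, a progenitor transcription factor, was at FPKM 162.5 and 389.6. Lower genes included Medag with 3113 and 691 reads, Tnfrsf21, a death receptor, with 4205 and 985, Spry1, a brake on receptor tyrosine kinase signalling, with 4690 and 1554, and Prelp, a matrix proteoglycan, with 2376 and 916. Of all genes with 3000 reads or more in total, list members included, 67 were 2-fold higher and 42 were 2-fold lower, of 3624.

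Reads from Y-linked genes were few in both libraries: Kdm5d had 32 and 165.4, Uty 47 and 27.7, Ddx3y 8 and 22, and Eif2s3y 3 and 13.

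The higher interferon gamma list was weighed against 4 explanations. More leukocytes in the sorted cells would bring their own transcripts, yet the pan-leukocyte median log2 read ratio was -0.003 (-0.002583 before rounding), with an upper quartile of 0.41 against a lower quartile of 1.86 for the interferon gamma members. Scaling or pseudocount choice is argued against too, since the lowest list median over the 7 such alternatives was 0.82. Few sampled molecules per gene would spread random lists matched on total reads as widely, and their highest median was 0.46 against 2.25 for the list. Differences between tumours, whatever the host, cannot be told apart from the host genotype with 1 library per genotype. Whether a library held 1 tumour or a pool is not given in the sample titles. An effect of the host genotype therefore stays open and untested, and replicate tumours of each host would decide.

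The spread between the libraries was 8.30 to 8.98 times counting error among genes with 100 to 3000 reads in total. If few molecules were copied many times, this factor would be about constant, but it was 9.46 from 3000 to 10000 reads and 14.4 above, and over all 5 classes the highest was 1.74 times the lowest, which leaves this explanation open; it had been read from the classes under 3000 reads alone before. Expression differences of the same size at every depth are argued against, since the spread itself differed 3.28-fold between the 3 classes from 100 to 3000 reads. Reads shared between genes are argued against by genes with whole reads in both libraries, whose factor was 8.32 in the class from 300 to 1000 reads. Low molecular complexity after the sort may add to the differences of single genes, and with 1 library per genotype it cannot be told apart from differences between the tumours.

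The lower collagen and matrix list was weighed against 3 explanations. Few sampled molecules per gene are argued against, since the lowest median of random lists matched on total reads was -0.39 against -0.57 for the list. Fewer fibroblasts stay open: the median log2 read ratio of the fibroblast markers was -0.28, with quartiles of -0.59 and 0.04. Pdgfra, at 5834 and 5056 reads, was nearly unchanged in proportion to the library totals of 26069378 and 23381862 reads. Fewer pericytes or smooth muscle cells were left open as well, with a median of -1.74 and quartiles of -2.26 and -0.35 over 6 markers of which 1 was 2-fold higher and 4 were 2-fold lower. That test first came out in favour of fewer pericytes. The condition that no marker be 2-fold higher, which Gja4 fails, was added after this result was seen. Without that condition these markers would count for fewer pericytes or smooth muscle cells. The host genotype, the tumour or tumours sampled and the share of stroma cannot be separated here.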
